A study of Mus musculus with 2 samples.

How the data were processed

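H3K4me3 was measured by ChIP-seq in mouse forebrain at embryonic day 15.5, in 2 biological replicates of pooled embryos of strain B6NCrl, per the labels. Library fragments ranged from 300 to 500 bp, per the labels. The deposited files were 4 peak lists on the mm10 assembly: 1 list per replicate, 1 called on both replicates together, and 1 of replicated peaks derived from these. The lists have no header line. The aligner, the peak caller, their settings and the overlap rule of the replicated list are not given in the sources used here.

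Each deposited list gave the position, the summit and a signal value of each peak in column 7. The design fixed beforehand took that deposited signal for a fold enrichment; what it is relative to is not stated, so it was called signal value and used only to rank and describe peaks within a list. The deposited lists also gave −log10 of a p-value and of a q-value per peak. The lowest −log10 p was 2.00 in replicate 1 and 2.02 in replicate 2, and 74.9% and 74.7% of their peaks had a −log10 q of at least 5. Read numbers were not part of these lists, so depth is unknown, binomial intervals cover counting of peaks only, and a difference in depth between the replicates could not be examined.

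Peaks on the 19 autosomes and X and Y were analysed; 18, 15, 17 and 12 peaks on other sequences were left out of replicate 1, replicate 2, the pooled and the replicated list. A peak counted as shared when a peak of the other list covered at least 50% of either. Chance sharing was estimated with 100 circular shifts along each chromosome. The build of the GENCODE vM21 annotation and of the RefSeq sequence, GRCm38, is that of mm10. A start window was 1 kb on either side of any transcript start of a protein-coding gene, 21853 genes in all, and a gene was marked when a peak overlapped a window. Peaks with gaps of up to 1000 bp were joined into domains, and a gene took its widest domain and its strongest peak. Several genes can share a domain, and a peak can reach the start of a neighbouring gene. Peaks outside start windows were placed by their summit. A start was CpG-rich with at least 50% GC and an observed to expected CpG ratio of at least 0.6 within 500 bp on either side.

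28 gene lists, chosen from general knowledge of the tissue, held markers of forebrain cell types, of other cells a dissection could hold, and of other tissues. 1 symbol (Ahsp) was not found, and 5 imprinted noncoding genes were kept out of the tests. Ttr was in the choroid plexus and the liver list, and Cspg4 in the oligodendrocyte and the endothelium list. The share of marked genes was compared with all other protein-coding genes by Fisher's exact test, two-sided. For lists with at least 10 marked genes, the median domain width and the median signal percentile within the list of peaks were compared with 100000 random draws of as many marked genes, two-sided. Each family of tests was adjusted by Benjamini and Hochberg's method with a threshold of 0.05. These tests compare genes within 1 tissue and treat genes as independent; neighbouring genes of a cluster are not. Values per replicate are given as mean ± SD of both replicates.

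Tests, gene lists and the rule for named genes were fixed before the data were examined. Named were per list the 4 marked members with the widest domains, up to 5 marked members where under 20% were marked, and up to 3 unmarked members in alphabetical order where over 50% were marked. The rule added the 10 widest domains, the 10 highest signals, 5 genes per replicate marked only there, and the 5 strongest peaks over 10 kb from any start. Foxg1 is named beside Gm43517, the gene nearest the centre of their shared domain. Other names under a shared peak were added after the values were seen.

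Alternatives set beforehand were other overlap rules, a −log10 q of at least 5, lists of equal length, windows of 500 and 2500 bp, the 5'-most start only, the pooled list, each replicate's list alone, a CpG-rich background, no joining or gaps of up to 3 kb, and ranking by −log10 p. The overlap and joining functions were checked against bedtools 2.31.1. The list tests were tested on simulated data drawn from the replicated list's 21853 genes, with 100 lists of 25 genes each. Of random lists, 4% had p under 0.05 for share (Fisher's exact test) and 4% for width (permutation test). Of lists with 80% of their genes drawn from wide domains, 92% had p under 0.05 for width (permutation test). Lists of raised share all held 92% marked genes, the lowest share among the lists called higher. All of them gave the same Fisher table, so that 100% had p under 0.05 was fixed in advance. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, and matplotlib 3.10.9 for figures.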

Results

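Trimethylation of lysine 4 of histone H3 (H3K4me3), a mark of nucleosomes at the starts of genes, was profiled by chromatin immunoprecipitation and sequencing in the forebrain of mouse embryos of strain B6NCrl at 15.5 days. The samples formed 1 group with 2 biological replicates, each a pool of embryos of mixed sex: 78 embryos in replicate 1 and 62 in replicate 2. The series therefore held no contrast between conditions, and the comparisons were those between the replicates, between genomic locations and between groups of genes within the tissue. On the 21 assembled chromosomes of mm10, replicate 1 had 28291 peaks covering 37.3 Mb and replicate 2 had 28888 peaks covering 39.0 Mb. The list called on both replicates together had 29404 peaks, and the replicated list, drawn from that pooled list, had 23895 peaks covering 40.3 Mb or 1.48% of the chromosomes. The number of reads behind each list is unknown, and so no interval that needs read depth was computed.

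The widest H3K4me3 domain lay at Pou3f3, and domains at Foxg1 and at Dlx5 with Dlx6 followed. The domain at Pou3f3, a POU factor of upper-layer cortical neurons, spanned 31.7 kb (chromosome 1, 42682963 to 42714682), and measured 31.5 ± 0.250 kb in the replicates (SD, n = 2). The domain that covered Foxg1, a forkhead factor required for telencephalon growth, together with the neighbouring gene model Gm43517, spanned 29.1 kb (chromosome 12, 49373207 to 49402270) and 29.4 ± 0.915 kb in the replicates (SD, n = 2). Dlx6 and Dlx5, homeobox genes of GABAergic neuron precursors, lay together under 28.6 kb (chromosome 6, 6854255 to 6882852), which covered both gene bodies, and 29.2 ± 0.823 kb in the replicates (SD, n = 2). The other 7 of the 10 widest domains lay at Meis2 (25.5 kb), Nfib (25.4 kb), Nr2f2 (23.3 kb), Nr2f1 (23.2 kb, and 20.7 ± 4.99 kb in the replicates, SD, n = 2), Dlx1 (22.8 kb), Mn1 (20.3 kb) and Bcl11a (18.7 kb), against a median of 2300.5 bp over all genes with a peak at a start. The highest signal values lay at other genes: Mrpl3, a mitochondrial ribosomal protein (78.6), Eif4a1, a translation initiation helicase (77.2), Hnrnpu, an RNA-binding protein (76.9), Zfp629 (76.9), Arl8a (76.8), Actg1, a cytoplasmic actin (76.3), Tra2a (75.9), Hsbp1 (75.9), Ptpn12 (75.6) and Upf1 (75.4). Of these 10 genes, Mrpl3 had a domain of 1.49 kb and Actg1 one of 6.56 kb, and none was among the 10 widest.

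**Figure D1:**
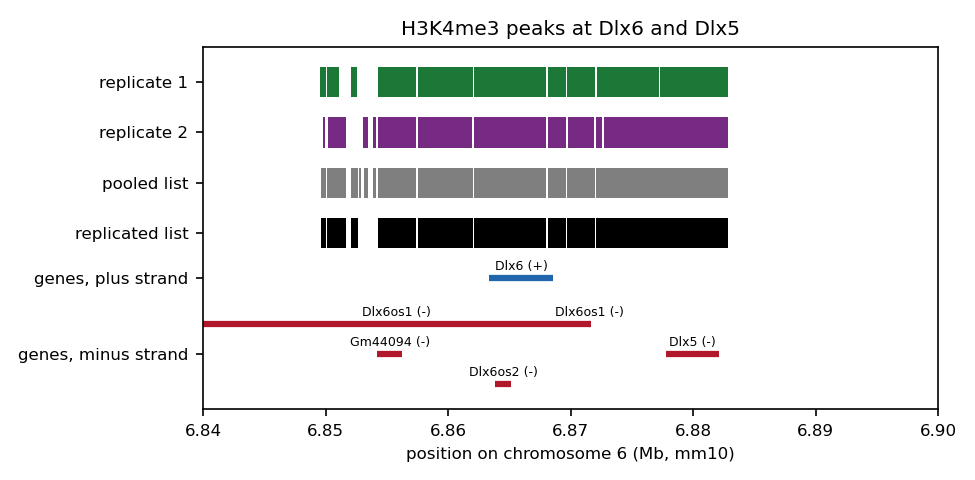
Peaks of the 4 lists (boxes) and annotated genes on each strand along chromosome 6 (position in Mb, mm10) around Dlx6 and Dlx5. In the replicated list, peaks separated by short gaps form the 28.6 kb domain from 6854255 to 6882852.

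Every member of 6 lists, those of cortical and intermediate progenitors, layer neurons, ganglionic eminence and interneurons, pan-neuronal genes, and synapse and channel genes, had a peak at a start. The domains of each of these lists were wider than those of other marked genes. All 20 cortical progenitor genes were marked, with a median domain of 8167 bp; besides Foxg1, the widest lay at Sox2, a neural stem cell factor (18.5 kb), Pax6, a patterning factor of the dorsal telencephalon (16.3 kb), and Lhx2, a cortical selector gene (14.1 kb). In the replicates the widths were 23.1 ± 7.53 kb at Sox2, 16.3 ± 0.523 kb at Pax6 and 18.0 ± 4.86 kb at Lhx2 (SD, n = 2). Replicate 1 had 28.4 kb at Sox2 and 21.5 kb at Lhx2. All 22 genes of deep and upper layer neurons were marked, with a median of 8279 bp, led after Pou3f3 and Nfib by Bcl11b, a factor of subcerebral projection neurons (16.5 kb), and Pou3f2 (15.8 kb). All 24 genes of the ganglionic eminences and of interneurons were marked, with a median of 8435 bp. The 12 intermediate progenitor genes had a median of 4521 bp, with Insm1 at 9.38 kb, Eomes, a marker of these progenitors, at 6.46 kb, Btg2 at 5.02 kb and Neurod1 at 4.91 kb. The 20 pan-neuronal genes had a median of 4859.5 bp, with Crmp1 at 8.68 kb, Tubb3, the neuronal tubulin, at 7.92 kb, Ina at 7.07 kb (its peak also reached the start of Nt5c2) and Dpysl3 at 6.06 kb. The 29 synapse and channel genes had a median of 3630 bp, with Slc17a6, a vesicular glutamate transporter, at 12.4 kb, Grin2b, a glutamate receptor subunit, at 8.64 kb, Dlg4 at 7.21 kb and Gria2 at 6.46 kb. Adjusted p for a higher share of marked genes ranged over these 6 lists from 2.87e-05 for synapse and channel genes to 0.0158 for intermediate progenitor genes (Fisher's exact test, two-sided, adjusted over 28 lists). Adjusted p for width was 4e-05 for each of them except intermediate progenitor genes, at 0.000108 (permutation test, two-sided, 18 lists with at least 10 marked genes). The smallest p these permutations can give before adjustment is 2e-05. Against CpG-rich genes alone, all 6 calls for share ended (adjusted p = 1, Fisher's exact test), where 98.9% of all such genes were marked and a list could hardly stand higher. The members without a CpG-rich start were all marked too, against 31.2% of the 10913 protein-coding genes without one. A CpG-rich start, as defined here, therefore cannot account for the mark at those members.

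At least 92% of the members of each list with more general functions were marked. All 27 chromatin regulator genes were marked, with a median domain of 3530 bp (adjusted p = 0.000295, permutation test) and the widest at Setd1b, an H3K4 methyltransferase (13960 bp), and Kdm6b, an H3K27 demethylase (12.8 kb). Arid1a (8.75 kb) and Arid1b (7.77 kb), subunits of a nucleosome remodelling complex, followed. All 19 immediate early genes were marked, with a median of 4267 bp (adjusted p = 4e-05, permutation test), led by Nr4a3 (7.63 kb), Nr4a2 (6903 bp), Egr3 (6.68 kb) and Fosl2 (6.63 kb). Of 25 morphogen and signalling genes 23 were marked, with a median of 4361 bp (adjusted p = 4e-05, permutation test); Dll1, a Notch ligand, had 10.1 kb, Wnt5a 8.36 kb, Wnt7b 8.06 kb and Cdon 7.99 kb. Fgf17 and Wnt8b had no peak in the replicated list, though Fgf17 had one of 0.18 kb in replicate 1's. Of 25 imprinted protein-coding genes 23 were marked, with a median of 3533 bp (adjusted p = 0.0006, permutation test), led by Gnas (9.86 kb, and 7.83 ± 2.11 kb in the replicates, SD, n = 2, with 6.34 kb in replicate 2), Peg3 (6.86 kb, with Usp29 under the same peak), Mest (6.28 kb) and Zrsr1 (4.68 kb). Ndn and Rtl1 had no peak. All 24 cell cycle genes were marked, with a median of 2847 bp that did not pass the width test (adjusted p = 0.0655, permutation test); Ccnd2 had 7.91 kb, Ccnd1 6.17 kb, Mki67 4.37 kb and Mcm7 4.15 kb (with Ap4m1 under the same peak). Cell cycle genes did pass in replicate 2's list (adjusted p = 0.00782), in the pooled list (adjusted p = 0.0141), without joining of peaks (adjusted p = 0.0183) and with each domain counted once (adjusted p = 0.043, permutation tests), over a range of 0.00782 to 0.0859 in all alternatives. All 25 ribosomal protein genes were marked, with a median of 2731 bp that did not pass it either (adjusted p = 0.13, permutation test); Rps15 had 11.2 kb, though 6.55 ± 6.52 kb in the replicates (SD, n = 2). Rps2 (5.87 kb, but 2.77 kb in replicate 1, with Rnf151 under its peak), Rpl4 (3.94 kb, with Zwilch) and Rpl3 (3.70 kb) followed. The higher shares of these 6 lists had adjusted p from 6.27e-05 for chromatin regulators to 0.00458 for morphogen and imprinted genes (Fisher's exact test, two-sided). With the 5'-most start of each gene alone, imprinted genes no longer passed for share (adjusted p = 0.123, Fisher's exact test) or width (adjusted p = 0.0955, permutation test); over all alternatives adjusted p ranged from 0.00157 to 1 for share and from 4e-05 to 0.0955 for width.

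Most genes listed as regulators of midbrain, hindbrain and spinal cord were marked, at low signal. Whether these genes are also expressed in parts of the forebrain was not measured. Of 25 regulators of midbrain, hindbrain and spinal cord 23 were marked (adjusted p = 0.00458, Fisher's exact test), and Evx1 and Phox2b were not. Their median signal stood at the 31.7th percentile of the replicated list, against 72.8 for all marked genes (adjusted p = 9e-05, permutation test). The widest lay at Gata2 (3.67 kb, signal 8.50), Lmx1b (3.43 kb, signal 8.96), Gata3 (2.93 kb, signal 10.2) and Atoh1, a factor of rhombic lip precursors (2.82 kb, signal 17.7). Of 39 Hox genes, which pattern the trunk and hindbrain, 18 were marked, with narrower domains (median 991 bp, adjusted p = 4e-05, permutation test) and lower signal (percentile 21.2, adjusted p = 9e-05, permutation test). Hoxa4 had 1.39 kb, Hoxd8 1.28 kb, Hoxd1 1.27 kb and Hoxd11 1.22 kb. Of 31 regulators of non-neural organs 20 were marked, with a median domain of 1534.5 bp (adjusted p = 0.00244, permutation test) and a median percentile of 30.5 (adjusted p = 9e-05, permutation test). Gata6 (3.42 kb), Eya1 (3.32 kb), Tbx1 (3.09 kb, but 1.59 kb in replicate 1) and Six1 (2.86 kb) were the widest, and Cdx2, Hand1 and Hnf1a had no peak. The Hox share of 46.2% was lower than that of other genes in the replicated list (adjusted p = 0.0235, Fisher's exact test), but was 56.4 ± 7.25% in the replicates (SD, n = 2) and did not pass in replicate 1's list (adjusted p = 0.121), replicate 2's (adjusted p = 0.69), the pooled list (adjusted p = 0.971) or with 2500 bp windows (adjusted p = 0.505, Fisher's exact test; lowest over the alternatives 1.41e-19). The midbrain, hindbrain and spinal list no longer passed for share with the 5'-most start of each gene alone (adjusted p = 0.123, Fisher's exact test; 0.00157 to 1 over the alternatives). Its median width of 1988 bp (adjusted p = 0.248, permutation test) became narrower than that of all marked genes without joining of peaks (adjusted p = 0.0178) and wider with gaps of up to 3 kb joined (adjusted p = 0.00786, permutation test).

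Genes of microglia and of differentiated cells of other tissues were rarely marked. Of 18 microglia and macrophage genes 2 were marked, Irf8 (1.40 kb) and Hexb (1.19 kb), as were 4 of 15 erythroid genes, Tal1 (1.90 kb, but 3.28 kb in replicate 1), Klf1 (1.39 kb), Gypa (0.832 kb) and Nfe2 (0.543 kb). Of 18 liver genes, Apoh alone was marked, under a 3.52 kb domain whose peak also reached the start of Prkca. Of 20 striated muscle genes 2 were marked, Mylpf (4.32 kb, with Tbc1d10b under the same peak) and Ryr1 (0.756 kb). Of 17 sensory and skin genes 3 were marked, Lor (2.64 kb), Krt10 (2.04 kb) and Otof (0.302 kb), and of 19 germline genes Boll (1.28 kb), Dazl (0.876 kb) and Tdrd1 (0.288 kb), the last absent from replicate 1's list. Of 1134 olfactory receptor genes 3 were marked, Olfr94 (1204 bp), Olfr1033 (0.391 kb) and Olfr658 (0.383 kb). Adjusted p for the lower share was 0.00641 for erythroid genes, 0.000211 for sensory and skin genes, 6.27e-05 for germline genes, 2.33e-05 for microglia, 4.66e-06 for muscle and 2.84e-06 for liver, and lowest for olfactory receptors (Fisher's exact test, two-sided). Among CpG-rich genes alone, the calls for microglia, erythroid, liver, muscle, and sensory and skin genes ended (adjusted p = 1, Fisher's exact test), with a difference of 1.09 percentage points. These lists held only 1 or 2 CpG-rich genes each, too few for that test to pass with all of them marked. Nearly all their members thus lacked a CpG-rich start, and 31.2% of all such protein-coding genes were marked. The shares of these lists ran from 5.56% for liver to 26.7% for erythroid genes. No test compared them with genes lacking a CpG-rich start, so their lower shares were not separated from CpG content. The germline genes still passed among CpG-rich genes alone (adjusted p = 6.13e-06, Fisher's exact test).

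Markers of glia, vessels, meninges and choroid plexus fell between these groups, and none of their shares differed from other genes by the test. Of 14 oligodendrocyte lineage genes 8 were marked (adjusted p = 0.676, Fisher's exact test), including Pdgfra, a receptor of oligodendrocyte precursors (6.80 kb, but 4.48 kb in replicate 2), Nkx2-2 (2.43 kb, but 0.31 and 1.87 kb in replicates 1 and 2), Mbp (2.12 kb) and Ugt8a (2.11 kb). The myelin genes Mag and Mobp and the receptor Gpr17 had no peak. Of 13 astrocyte genes 9 were marked, led by Fgfr3 (5.68 kb), Slc1a2 (4.15 kb), Gja1 (3.23 kb) and Slc4a4 (2.73 kb). Agt, Aqp4 and Gfap, the astrocyte intermediate filament, had no peak. Of 20 endothelium and pericyte genes 13 were marked, with Foxc1 at 6.65 kb (4.93 ± 2.47 kb in the replicates, SD, n = 2), Foxf2 at 5.59 kb, Flt1 at 2.99 kb and Kdr, a receptor for VEGF, at 2.87 kb. In replicate 1 these 3 had 3.46, 1.82 and 1.76 kb. Cdh5, Emcn and Pecam1 had no peak in the replicated list, though Cdh5 had one of 0.222 kb in replicate 1's. Of 17 meningeal and mesenchymal genes 13 were marked (adjusted p = 0.545, Fisher's exact test), with Zic1 at 11.6 kb (Zic4 lay under the same peak), Prrx1 at 4.25 kb, Msx1 at 3.85 kb (1.91 kb in replicate 1) and Fn1 at 2.83 kb. Col3a1, Dcn and Lum, genes of the extracellular matrix, had no peak in the replicated list, though Dcn had one of 0.213 kb in replicate 2's. Of 14 choroid plexus and cilia genes 9 were marked, with Otx2 at 5.67 kb, Rfx3 at 4.03 kb, Ccno at 2.70 kb and Foxj1 at 2.52 kb. Aqp1, Dnah5 and Folr1 had no peak. Adjusted p was 1 for astrocyte, endothelial, choroid plexus and non-neural regulator genes (Fisher's exact test). The clustered protocadherins had 43 of 57 genes marked (adjusted p = 0.159, Fisher's exact test, and 0.0104 to 1 over the alternatives, passing as a higher share in the pooled list), with a median domain of 605 bp (adjusted p = 4e-05, permutation test). Pcdhgc3 (5.80 kb), Pcdhgc4 (4.09 kb), Pcdhac2 (3.25 kb, but 2.14 kb in replicate 1) and Pcdhga11 (2.93 kb) were the widest, and Pcdha1 and Pcdha8 had no peak. Of the 2 gene models annotated as Pcdha11 on chromosome 18, the one starting at 37005203 had no peak and the one starting at 37010712 had a domain of 0.35 kb.

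**Figure D2:**
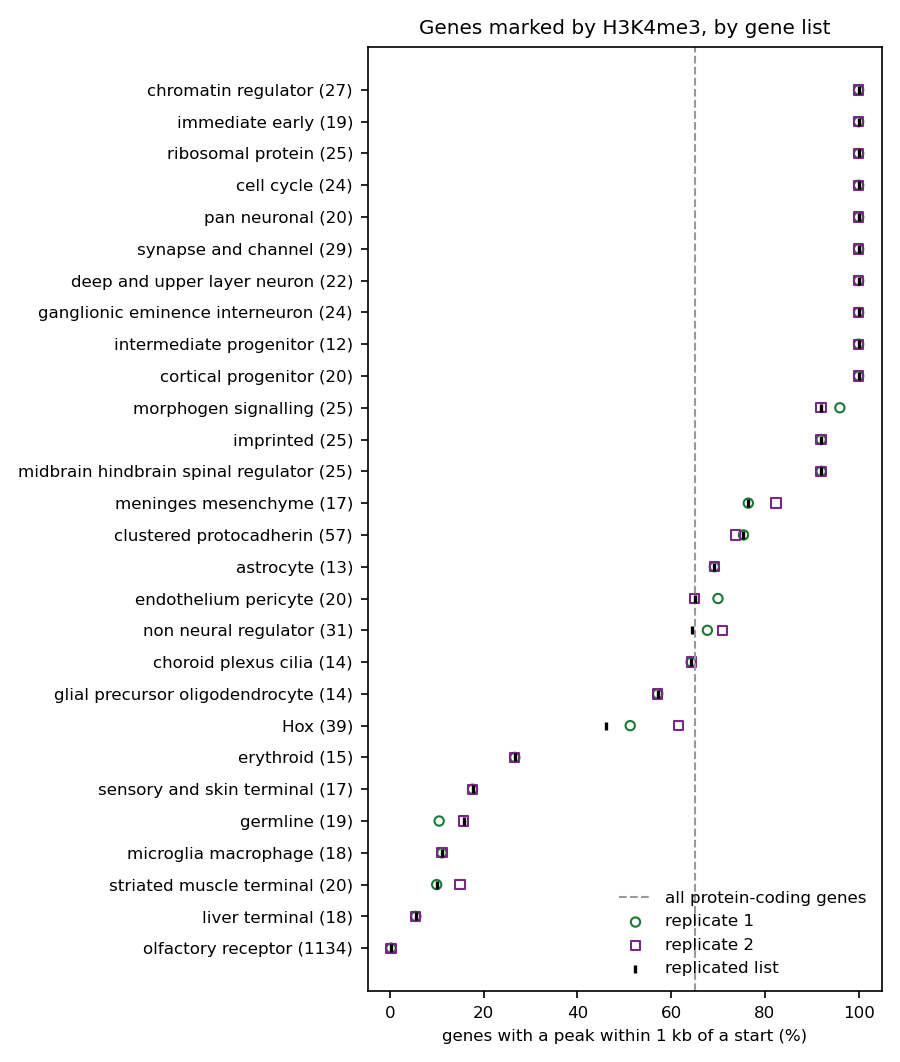
Percent of genes in each of 28 lists with a peak within 1 kb of a start (number of genes in brackets), as 1 circle and 1 square for the replicates and a bar for the replicated list. The dashed line is all protein-coding genes in the replicated list, 65.1%; 10 lists stand at 100% and olfactory receptors at 0.265%.

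**Figure D3:**
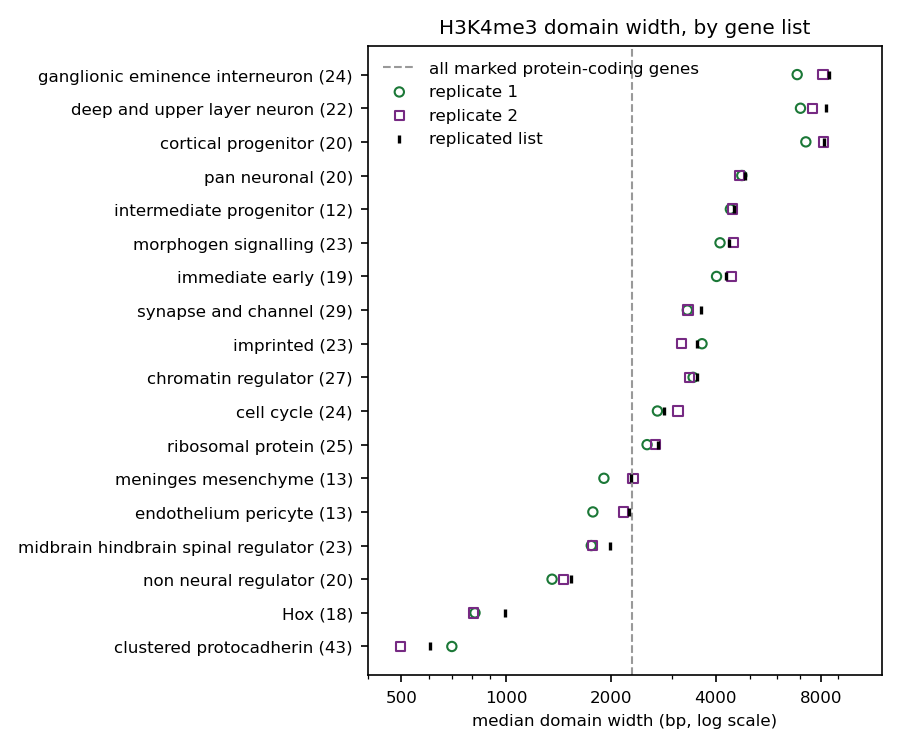
Median H3K4me3 domain width in bp (log axis) of the marked genes of 18 lists (number of marked genes in brackets), as 1 circle and 1 square for the replicates and a bar for the replicated list. The dashed line is the median of all marked genes, 2300.5 bp; the 3 lists of forebrain progenitors, layer neurons and ganglionic eminence genes lie at 8167 bp or above in the replicated list.

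Signal values ordered the lists differently from widths. Chromatin regulators alone had a higher signal percentile than other marked genes, with a median of 88.3 against 72.8 (adjusted p = 0.00288, permutation test), though not when peaks were ranked by their −log10 p (adjusted p = 0.0543; 0.000288 to 0.0543 over the alternatives). Ganglionic eminence and interneuron genes had wide domains but a lower percentile, 51.7 (adjusted p = 0.00084, permutation test); the strongest peaks of Dlx5 and Dlx6 stood at 51.5 and 52.8. Lower percentiles were also found for clustered protocadherins (22.5, adjusted p = 9e-05), endothelium (42.2, adjusted p = 0.00084), meninges (43.7, adjusted p = 0.00113), imprinted genes (57.1, adjusted p = 0.0193) and morphogen genes (58.8, adjusted p = 0.0375, permutation tests), besides the Hox, midbrain to spinal and non-neural regulators above. The imprinted list did not pass in replicate 1's list (adjusted p = 0.0801, permutation test; 0.00684 to 0.0801 over the alternatives). Cortical progenitor genes (65.2, adjusted p = 0.308), layer neuron genes (71.5, adjusted p = 0.829), pan-neuronal genes (76.3, adjusted p = 0.604), synapse genes (64.8, adjusted p = 0.202), intermediate progenitor genes (56.3, adjusted p = 0.06), immediate early genes (66.1, adjusted p = 0.38), cell cycle genes (68.4, adjusted p = 0.516) and ribosomal protein genes (81.7, adjusted p = 0.153, permutation tests) did not pass the test. Layer neuron genes passed as lower with the 5'-most starts (adjusted p = 0.0479, permutation test; 0.0479 to 0.981 over the alternatives). Endothelial and meningeal genes did not pass for width (adjusted p = 0.949 and 0.957, permutation test).

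Across all 21853 protein-coding genes, 14224 or 65.1% had a peak within 1 kb of a start, and 65.3 ± 0.133% in the replicates (SD, n = 2). The share differed by sequence: 98.9% of the 10940 genes with a CpG-rich start were marked, against 31.2% of the 10913 others. Among CpG-rich genes alone, that level left a list hardly any room for a higher share, and 0 lists had one (Fisher's exact test; also 0 at an unadjusted p under 0.05), so that all calls for a higher share ended. Olfactory receptors had no CpG-rich member. A lower share was found for Hox genes (adjusted p = 1.41e-19), germline genes (adjusted p = 6.13e-06) and non-neural regulators (adjusted p = 0.00964, Fisher's exact test). On chromosome Y, 4 of 183 genes were marked, and on chromosome X 482 of 948.

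Most of the mark lay at starts of protein-coding genes. In the replicated list, 14404 peaks or 60.3% overlapped such a start window, compared with 4.37% on average after 100 circular shifts of the peaks, and they held 80.4% of the covered base pairs. The share was 53.6 ± 0.616% in the replicates (SD, n = 2). Starts of noncoding genes took 5.77% of replicated peaks, exons 5.04%, introns 14.3% and intergenic sequence 14.6%. The share at protein-coding starts was 13.8% in the lowest and 98.4% in the highest of 10 equal classes of peaks by signal. Summits lay downstream of the nearest start in 83.2% of 14360 peaks, at a median of 145 bp (quartiles 61 and 264 bp), with 141 and 145 bp in replicates 1 and 2.

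**Figure D4:**
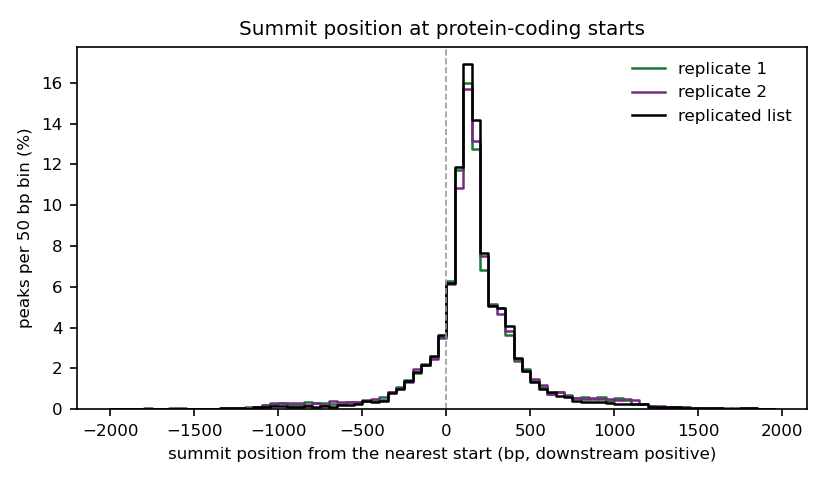
Position of peak summits from the nearest protein-coding start (bp, downstream positive) as percent of peaks per 50 bp bin, for both replicates and the replicated list. The highest bin starts at 100 bp in each and holds 16.9% of peaks in the replicated list.

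The replicates shared their strong peaks and differed in weak ones. Of replicate 1's peaks 86.0% (95% exact binomial interval 85.5 to 86.4) were shared with replicate 2, and of replicate 2's 81.8% (81.4 to 82.3) with replicate 1, against 2.11% and 2.05% on average after circular shifts. Every peak in the upper 6 of 10 signal classes of either list was shared, while in the lowest class 39.9% of replicate 1's and 29.7% of replicate 2's were. Unshared peaks had median widths of 221 and 238 bp, and 16.4% and 16.2% of them lay at protein-coding starts. At the level of genes, 14176 were marked in both replicates, 66 in replicate 1's list alone and 107 in replicate 2's alone. Outside the replicated list, the strongest such genes were Pm20d1, Gimap9, Fndc9, Grap and 9030025P20Rik in replicate 1 (signal 3.62 to 4.47), and Cldnd2, Hpn, Lefty2, Pgr15l and Slc47a1 in replicate 2. The peaks assigned to Cldnd2 (signal 36.6), Hpn (6.01) and Lefty2 (5.35) were shared with replicate 1, where their edges lay outside the start window. Across the genes marked in both, which are not independent replicates, domain widths had a Spearman correlation of 0.934, and the median difference between replicates was 8.05%.

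**Figure D5:**
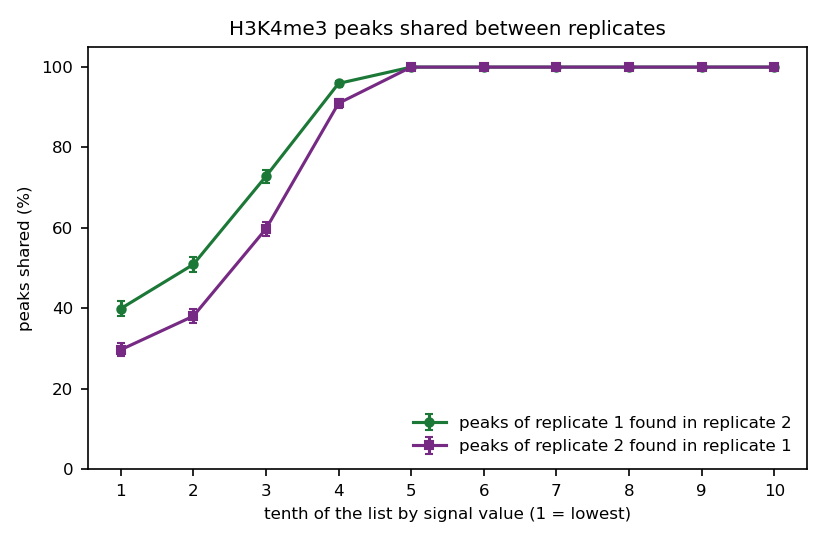
Percent of each replicate's peaks shared with the other replicate, by class of signal value (10 classes of equal size per list, 1 lowest), with 95% exact binomial intervals. From class 5 upward 100% were shared; in class 1 the shares were 39.9% and 29.7%.

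Of the 29404 pooled peaks, 81.3% (95% exact binomial interval 80.8 to 81.7) were kept in the replicated list, and all 23895 replicated peaks were identical to pooled ones. Those not kept had a median signal of 2.51 and a highest of 4.74. Pooled peaks that met the overlap rule used here in both replicates numbered 22771, all of them in the replicated list, which held a further 1124 peaks that did not meet it.

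The 5 strongest replicated peaks over 10 kb from any annotated start were present in both replicates, as were strong peaks in general. The strongest had the pseudogene Gm47110 as its nearest annotated gene (chromosome 9, 67631701 to 67634718, signal 65.4). The others lay 33.2 kb from Pum2 (chromosome 12, 8640117 to 8641830, signal 64.8), 13.3 kb from Gpr161 (chromosome 1, 165280703 to 165284398, signal 62.7), 13.5 kb from Fcgr3 (chromosome 1, 171043665 to 171045817, signal 61.5) and 26.1 kb from Egr1 (chromosome 18, 34886865 to 34888502, signal 57.6). None had its summit inside an annotated gene, and the peak nearest Pum2 was 52.3% repeat-masked sequence. The 3162 replicated peaks this far from a start had a median signal of 5.47 and a median width of 591.5 bp.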

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

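The replicated list held 12 peaks on sequences outside the assembled chromosomes, which no comparison used. They lay on 6 such sequences, with a median signal of 14.3 and a highest of 52.9. The pooled list held 17 peaks there. No explanation was tested.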

How the results depend on the processing

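Alternatives were set beforehand except counting each domain once, matching on the number of starts and the CpG ratio, and leaving out olfactory receptors, which were chosen after seeing the data. No paired analysis was possible because the series has 1 group. The cause of the changes was not tested except where the alternative's construction shows it. Read depth is unknown, so whether it limits how many weak peaks each list holds could not be examined.

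Sharing of replicate 1's and replicate 2's peaks was 88.6% and 84.3% at 1 bp of overlap, 76.5% and 74.9% at 50% of both peaks, and 95.4% and 92.6% at a −log10 q of at least 5; with lists of equal length replicate 2's was 83.1%. Pooled peaks were kept at 97.1% with a −log10 q of at least 5, a filter that removes weak peaks. Peaks at protein-coding starts, and genes marked, were 58.7% and 64.6% with 500 bp windows, 66.2% and 66.2% with 2500 bp, 52.9% and 62.4% with the 5'-most start, 62.6% and 64.9% at a −log10 q of at least 5, and 51.7% and 65.6% in the pooled list. With either replicate left out they were 53.2 to 54.1% and 65.2 to 65.4%. With a CpG-rich background 0 lists had a higher share, since nearly all such genes are marked, and 3 a lower one against 8. The 6 lost lists held 0 to 2 CpG-rich genes each, and non-neural regulators were gained; ranked by −log10 p, 0 lists had a higher signal (1 at an unadjusted p under 0.05). The other counts of lists stayed within 1.5 times.

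Of 592 values of single lists under alternatives, 535 kept direction and side of the threshold, and 28 turned direction. Of those that kept direction, 21 lost and 8 gained a call. Some that turned also lost or gained a call, such as the share of microglia genes with a CpG-rich background. With a CpG-rich background the difference in share became 1.09 points for oligodendrocyte, microglia, endothelium, choroid plexus, erythroid, liver, muscle and skin genes and −3.92 for midbrain to spinal regulators. Endothelium turned to 0.364 with 500 bp windows, 0.121 at a −log10 q of at least 5 and −0.36 to 4.83 with a replicate left out. Non-neural regulators turned to 4.79 with 2500 bp, 5.34 in the pooled list and 2.57 to 5.62 with a replicate left out. Protocadherins turned to −1.73 at a −log10 q of at least 5. The log2 width ratio of meningeal genes became 0.050 with 500 bp windows, 0.015 in the pooled list, −0.18 to 0.032 with a replicate left out, 0.042 without joining, 0.064 with gaps of 3 kb, 0.029 with each domain once and 0.11 matched. That of endothelium became 0.028 with the 5'-most start, 0.013 with each domain once and 0.17 matched. That of midbrain to spinal regulators became 0.53 with gaps of up to 3 kb (adjusted p = 0.00786, permutation test).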

Other observations

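Tests chosen only after the results were seen were those of symbol groups and pairs of lists, of widths with each domain once or with matched genes, of cells of other tissues or brain regions, of CpG content by separate lists, and of repeats. The share of noncoding genes with the mark differed widely by class, with no test of the difference. A peak lay within 1 kb of a start for 178 of 190 lncRNA genes at bidirectional promoters (93.7%) and 434 of 790 processed transcripts (54.9%). A peak lay within 1 kb of a start for 906 of 5854 lincRNA genes (15.5%), 1049 of 2959 antisense genes (35.5%), 319 of 2202 miRNA genes (14.5%) and 1.97% of 9940 processed pseudogenes. Away from protein-coding start windows the shares were 34.1% for processed transcripts (168 of 493), 10.7% for lincRNA, 15.5% for antisense, 7.60% for miRNA genes and 1.81% for processed pseudogenes. Only 6 of the 190 lncRNA genes at bidirectional promoters lay away from such windows, 5 of them marked. The imprinted noncoding genes H19, Meg3, Kcnq1ot1, Nespas and Airn each had a peak in all 4 lists.

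Groups of at least 20 genes with the same opening letters in their symbols were compared after the data were seen, 101 groups in all. By Fisher's exact test with adjustment, 50 had a higher and 26 a lower share of marked genes. Mediator subunits (Med, 30 of 30), RNA polymerase subunits (Polr, 28 of 28), mitochondrial ribosomal proteins (Mrpl, 49 of 49) and Zbtb factors (41 of 41) were all marked. Beta-defensins (Defb, 42 genes), major urinary proteins (Mup, 22 genes), secretoglobins (Scgb, 34 genes) and reproductive homeobox genes (Rhox, 34 genes) had no marked member, and vomeronasal receptors (Vmn) had 1 of 331. Histone genes (Hist) had wider domains, 3467 bp at the median (adjusted p = 0.000533, permutation test), as did semaphorins (Sema, 3693 bp, adjusted p = 0.0036, permutation test). The median signal percentile of histone genes was 49.3, against 72.8 for all marked genes. For these groups, widths were not tested without joining or with each domain counted once, so genes that share a joined domain may count repeatedly. Cilia and flagella genes (Cfap) had 28 of 31 marked but narrow domains, 1248 bp (adjusted p = 0.000533, permutation test).

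Ganglionic eminence genes had a lower median signal percentile than cortical progenitor genes, 51.7 against 65.2 (adjusted p = 0.00414, permutation test), and than layer neuron genes, 71.5 (adjusted p = 0.00856, permutation test). Their median widths of 8435, 8167 and 8279 bp did not differ by the test (adjusted p = 0.972 for both, permutation test). They exceeded midbrain to spinal regulators in width (8435 against 1988 bp, adjusted p = 0.00012, permutation test) and percentile (51.7 against 31.7, adjusted p = 2.67e-05, permutation test, where the smallest p before adjustment is 1e-05). These comparisons exchanged genes between lists.

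The 10 lists with wider domains include genes that share domains, such as Dlx5 and Dlx6. With each domain counted once, 10 of the 10 lists were still wider. The match for starts and CpG used the number of starts and the highest observed to expected CpG ratio within 500 bp of a start. Against marked genes so matched 10 of the 10 were wider, and with no joining of peaks 10 of the 10 were. These values argue against shared domains, against the number of starts with that ratio, and against joining, each as the whole cause. The length of CpG-rich sequence was not matched, so it stays open as a cause. Read depth and the mix of cell types in the tissue were not tested, and no biological explanation was tested since the series has 1 group.

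The marked Hox genes, midbrain to spinal regulators and non-neural regulators were weighed as a set of 95 genes, 61 of them marked. A CpG-rich start did not carry the mark whatever the gene. Of the 67 CpG-rich members 73.1% were marked (95% exact binomial interval 60.9 to 83.2), against 99.1% of other CpG-rich genes. The interval treats neighbouring Hox genes as independent, and the unmarked members do not show why the others were marked. By list the marked shares of CpG-rich members were 50% for Hox genes (14 of 28), 84.2% for non-neural regulators (interval 60.4 to 96.6) and 95% for midbrain to spinal regulators. CpG-rich sequence could account for the mark at the CpG-rich members of the last of these lists. It cannot at that list's 5 other members, of which 4 were marked. Over the whole set, 12 of the 28 members without a CpG-rich start were marked (42.9%), against 31.2% of all such protein-coding genes. A CpG-rich start, as defined here, cannot account for the mark at these 12, so it is argued against as the whole cause. For non-neural regulators the interval holds the 95% taken as the sign of this cause, so by that rule the share of CpG-rich members cannot tell. The interval leaves out the 99.1%, and their share was lower among CpG-rich genes by the Fisher's exact test above. Both rest on the same 19 genes and are not separate evidence. They show that CpG-rich members of this list were marked less often than other CpG-rich genes. The start of a protein-coding gene outside the set lay under the strongest peak of 1.64% of the marked members, too few for such genes to account for them. Neighbours within the set, such as adjacent Hox genes, were not counted. Starts of noncoding genes were not counted either, though some lay under these peaks, such as Hotairm1 at Hoxa1 and Haglr at Hoxd1. Both kinds of neighbour stay open. Cells of other tissues cannot be told apart from forebrain cells for the non-neural part: 11.4% of 70 terminal genes of blood, liver, muscle, skin and sense organs were marked away from other genes' starts (interval 5.07 to 21.3; 10 of 88 with microglia genes, which the set first held before it was narrowed after that value was seen), but so were 70.6% of meningeal, 64.3% of choroid plexus and 60% of endothelial genes. Cells of neighbouring brain regions cannot be told apart from forebrain cells for the midbrain to spinal part, 92% of which was marked. Of the Hox genes, which pattern the trunk and hindbrain, 18 of 39 were marked, which does not decide for hindbrain or spinal cells. No other list here separates midbrain from forebrain cells, and no biological explanation was tested.

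Of the peaks over 10 kb from any annotated start, 200 had a signal at or above the replicated list's median, and all 200 were in both replicates. Presence in both was largely set by this choice, since strong peaks were shared wherever they lay. Reads placed in repeat-masked sequence are argued against as the general cause, since 0.5% of these peaks were mostly repeat-masked, against 0.59% of all replicated peaks. The 1 peak that was is the one nearest Pum2. Duplicated sequence that is not masked was not examined. Starts missing from the annotation may account for part of them: 31.5% (63 peaks, interval 25.1 to 38.4) lay within 1 kb of a RefSeq transcript start, among them the peaks nearest Gm47110, Gpr161 and Fcgr3, against 9.35% of the weaker distal peaks. For the remainder, including the peaks nearest Pum2 and Egr1, the origin stays open, and no biological explanation was tested.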
